A study of Mus musculus with 6 samples.

How the data were processed

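RNA of megakaryocyte-erythroid progenitors (MEP), the bone marrow cells that give rise to platelet-forming and red cells, was measured on 6 Affymetrix arrays. Per the labels, the mice were C57BL/6, 3 arrays came from T-bet knockout mice and 3 from wild-type mice, and the cells were sorted by flow cytometry from fresh bone marrow after antibody staining. T-bet, encoded by Tbx21, is a transcription factor known for its part in T helper 1 and natural killer cells. Group and replicate number were taken from the sample titles, and the labels describe the arrays of a group as separate mice. Per the labels' protocols, total RNA was turned into biotin-labelled cRNA by the standard Affymetrix procedure.

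The deposited file holds 1 log2 signal per probe set and array for 41345 probe sets, made by the authors with Affymetrix Expression Console 1.4.1.46, per the submitters' processing notes. The background correction, the normalization and the summarisation of probes into probe sets are not given in the sources used here. The log scale and its base were inferred from the values: the highest value, 14.2, lies above 11.1, the natural log of the largest intensity a 16-bit scanner can record. Array medians lay between 6.44 and 6.53, so the arrays were used as deposited. Neither scanner intensities nor detection calls were used here, so which probe sets lay above background is unknown. Probe sets with a mean in the lowest 30% are called dim below, and a difference between dim values can understate a true difference.

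Names came from a table of the array's annotation. It listed 25335 of the probe sets, 23521 with 1 gene symbol and 1814 with several, and left 16010 unnamed here. Symbols were updated by gene ID through a RefSeq table of the GRCm38.p6 assembly, which held 23328 of the 23521. That table also gave each gene's chromosome and neighbours; no coordinates are printed because the array file names no build. Each of the 22180 genes was represented by its probe set of highest mean. The 6 values of 1399 probe sets were identical to those of another probe set, 433 of them in the annotation table.

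Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, knockout minus wild type, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The plan was to leave control probe sets out, but nothing in the tables used here marks them, so all 41345 stayed in the fit; a fit of the named probe sets alone was added. A second, descriptive count took probe sets with an unadjusted p under 0.01 and a difference of at least 1.5-fold. A total of 24 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Genes near Tbx21 on chromosome 11 were compared with all other placed genes by Fisher's exact test, 2-sided, within 10 Mb of Tbx21. Exact permutation tests were 2-sided, and with 3 arrays against 3 the smallest p they allow is 0.1. SE and 95% intervals are limma's; ± is the SD over the 3 arrays of a group.

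The samples, tests, lists and alternatives were fixed before the data were examined. So was the rule for naming genes. It took Tbx21, then up to 12 genes per direction past the adjusted threshold. Where fewer than 10 passed, a direction was filled to 10 with the smallest unadjusted p among genes at least 1.5-fold apart whose groups did not overlap, as values and not as changes. Predicted genes and Riken clones were skipped. It also took the 3 genes of smallest p in each list. Other genes named below are known members of their list or were singled out after their values were seen.

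The labels number the mice 1 to 3 in both groups without saying what a number shares. Deviations from the group means were therefore correlated between same-numbered arrays. Over 1 probe set per gene the correlations were 0.285, 0.116 and 0.115 for numbers 1, 2 and 3. Over probe sets outside the dim 30% they were 0.326, 0.106 and 0.227, and over all probe sets 0.212, 0.0569 and 0.140. All 6 arrays correlated best with their own number in each of these 3 sets. The criterion of 0.1 in every pair was met in the first and second set and missed by number 2 over all probe sets. The numbers were treated as pairs on the gene-level values. That choice among the 3 sets was made with all of them in view and after a first look at the blocked fit. Pairs enter only the replicate block and the passages on same-numbered arrays below. The main fit, its SE and intervals, the main camera tests and the exact permutation tests used no pairing. The fit with replicate number as a block called the same 3 lists and 0 probe sets.

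The statistics were tested on simulated data with 41345 probe sets and 50 changed probe sets per fold, all planted in the same data. At the adjusted threshold 15 of 50 were recovered at 1.5-fold, 27 at 2-fold, 48 at 4-fold and 50 at 8-fold, with 9 false calls. The unadjusted threshold recovered 23, 43, 50 and 50 of 50, with 166 false calls. A shift of 0.3 log2 added to the mitosis list, over 22180 genes, was recovered by camera, and 0 of the other lists were called. Every probe set was drawn independently. The simulation therefore cannot show how often camera calls lists whose genes vary together.

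The alternatives were a replicate block, a further quantile normalization, centring of each array on its median, limma-trend, array weights, removal of dim probe sets, other thresholds, other ways to represent a gene, windows of 5 and 20 Mb, and leaving out each array in turn. After the data were seen, 4 more were added: a block for the class of sex-linked signal, the 3 arrays with the signal of 1 sex alone (knockout replicate 3 against wild-type replicates 2 and 3), the named probe sets alone, and the replicate block with an estimated correlation. In the sex-linked block wild-type replicate 2 was alone in its class, so it added nothing to that fit's contrast. A larger offset before the log was not applied because the values were already on a log scale. The number of arrays limits the precision of every value.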

Results

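Gene expression was profiled in flow-sorted bone marrow MEP cells of 3 T-bet knockout and 3 wild-type mice, 1 array per animal according to the labels. Values are log2 signals of 41345 probe sets, and ± is the SD over 3 arrays. Array medians were 6.53, 6.45 and 6.44 in knockout replicates 1 to 3 and 6.51, 6.44 and 6.47 in wild-type replicates 1 to 3. Arrays of the same group correlated across probe sets at r = 0.980 to 0.987 (6 pairs), and arrays of different groups at 0.982 to 0.987 (9 pairs); probe sets are not independent replicates. The comparison asks which transcripts of these progenitors differ when T-bet is missing.

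Tbx21, the targeted gene, had a signal of 6.49 ± 0.10 in knockout and 6.58 ± 0.04 in wild-type arrays, a difference of -0.09 (SE 0.09, 95% interval -0.32 to 0.13). The exact permutation test gave p = 0.3. The 3 knockout values were not all below the 3 wild-type values, and which exons the probe set covers is not given in the sources used here. Tbx21 therefore gave no check of the genotype labels.

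The arrays did carry the signal of sex-linked genes, which was examined after the values were seen. Xist, the RNA that coats the inactive X chromosome of female cells, read 11.83 and 11.79 in knockout replicates 1 and 2 and 5.42 in knockout replicate 3. It read 11.81, 12.21 and 5.56 in wild-type replicates 1 to 3. The Y-linked translation factor gene Eif2s3y read 8.39, 8.86 and 9.73 in knockout replicates 1 to 3 and 8.78, 4.95 and 9.70 in wild-type replicates 1 to 3. Uty, a Y-linked histone demethylase gene, read 8.36, 8.47 and 9.74 in the knockout arrays and 8.68, 5.23 and 9.51 in the wild-type arrays. Knockout replicates 1 and 2 and wild-type replicate 1 thus carried both Xist and Y-linked signal, knockout replicate 3 and wild-type replicate 3 Y-linked signal alone, and wild-type replicate 2 Xist alone. The p-values of limma, fry and the exact permutation tests below measure the spread between these 6 arrays, whose description as single mice these values leave open. Camera's p-values at the preset correlation and those of Fisher's exact test compare genes with other genes. They do not measure the spread between arrays.

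**Figure D1:**
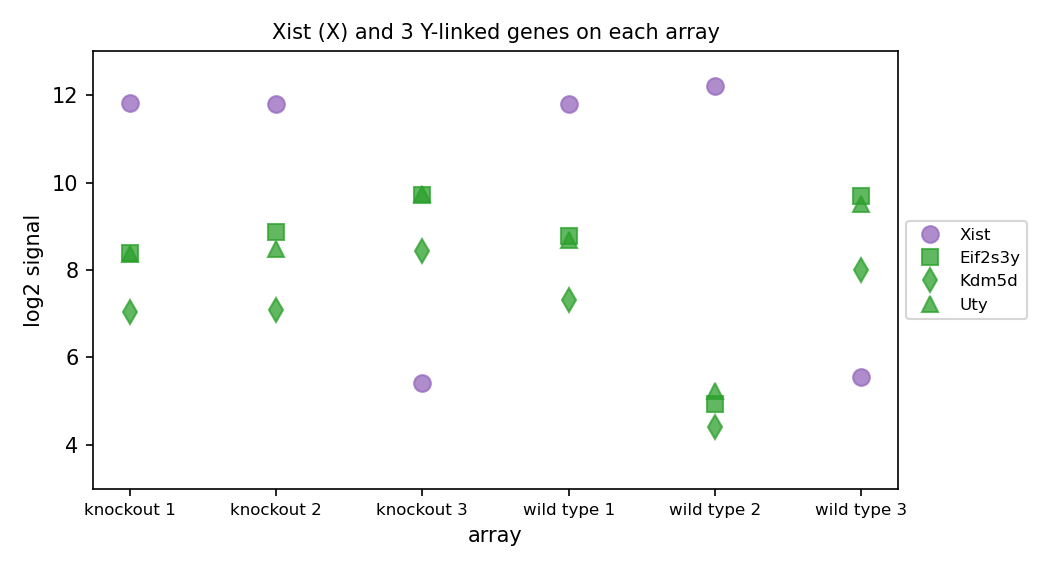
Log2 signal (vertical axis) of Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (horizontal axis), 1 point per gene and array. Xist lies between 11.79 and 12.21 on 4 arrays, and on 3 of these the Y-linked genes are also well above their level in wild-type replicate 2.

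No probe set passed limma's adjusted p of 0.05 (0 of 41345). The smallest limma adjusted p was 0.0537, for an unnamed probe set with ID 17206959. It read 4.73 ± 0.23 in knockout and 2.20 ± 0.19 in wild-type arrays, a difference of 2.53 (SE 0.16). Its wild-type values lay below the 10th percentile of those arrays, 4.29 to 4.40. Whether it is a control probe set is unknown here. At an unadjusted p under 0.05 there were 2033 probe sets, 1227 higher and 806 lower in the knockout, where chance alone gives 2067. At an unadjusted p under 0.01 there were 387, where chance alone gives 413. At an unadjusted p under 0.01 and at least 1.5-fold there were 180, of which 126 were higher and 54 lower. Unchanged probe sets of the simulated data gave 166 at this threshold. After a further quantile normalization the real count was 149, split 79 to 70. Of the 180, 151 were unnamed and 28 had 1 gene symbol, where 16010 of all 41345 were unnamed.

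Among named genes, those that met the unadjusted threshold were mainly chemosensory receptors at dim signals. All 10 higher genes taken by the naming rule encode odorant or vomeronasal receptors, families with many near-identical members; whether these probe sets also read related receptors was not tested. Olfr1274 read 3.67 ± 0.14 in knockout and 2.44 ± 0.28 in wild-type arrays, a difference of 1.22 (SE 0.16, limma adjusted p = 0.837). Olfr173, Olfr51 and Olfr44 differed by 1.00, 0.84 and 0.61, and Olfr1445 and Olfr907 by 0.70 and 0.59. The vomeronasal receptors Vmn1r64, Vmn1r69, Vmn1r49 and Vmn1r74 differed by 0.96, 0.98, 0.60 and 0.61. All 10 lay in the dim 30% of probe sets.

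The 10 lower genes taken by the rule were led by Rsad1, a radical SAM domain gene on chromosome 11, at 7.70 ± 0.08 in knockout and 8.33 ± 0.06 in wild-type arrays. Its difference was -0.63 (SE 0.09, limma adjusted p = 0.837), and it and Olfr1336, at -0.85, were the 2 of the 10 outside the dim 30%. The others were Olfr823 (-0.66), Mir743 (-0.75), Sprr2d (-0.83), Mir669b (-0.69), Acot1 (-0.74), Olfr910 (-0.63), Vmn1r13 (-0.60) and Nlrp4g (-0.64). The adjusted p of these 20 genes lay between 0.837 and 1. In all, 18 of the 26 genes past the unadjusted threshold were odorant or vomeronasal receptors, 69.2% against 6.28% of all genes. Of the 26, 88.5% were dim, against 26.5% of all genes. Fisher's exact test of the receptor share, run after the list was seen, gave p = 2.03e-16; it counts related receptors as independent and takes no account of dim signal, so it is not independent evidence of enrichment.

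For most genes the arrays bounded the difference in signal, which can understate a difference in RNA where signal is dim. The 95% interval lay within 2-fold in either direction for 21739 of 22180 genes (98.0%) and within 1.5-fold for 19047 (85.9%). Outside the dim 30% these were 16210 of 16296 genes (99.5%) and 15179 (93.1%). Tbx21, the targeted gene, was itself bounded within 1.5-fold. Whether its transcript differed in these cells is unknown here, so whether such a bound on signal holds for the transcript stays open. The groups did not overlap for 8.70% of genes, against 10% by chance. On simulated data of the same size the test recovered 48 of 50 probe sets changed 4-fold, 27 of 50 changed 2-fold and 15 of 50 changed 1.5-fold. These and 50 changed 8-fold were planted together, and many true changes ease the Benjamini-Hochberg cut-off. The rates can therefore overstate what the test finds where few probe sets change.

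Megakaryocyte and platelet genes were lower in the knockout as a group in camera's test. Of 36 measured members, 32 had a negative difference and 4 a positive one, with a median of -0.13 (adjusted p = 1.22e-05, p = 0.140 with an estimated correlation). F2rl3, a thrombin receptor gene, differed by -0.29 (SE 0.08), the calcium channel gene Trpc6 by -0.42 (SE 0.13), and P2rx1, the ATP-gated channel of platelets, by -0.57 (SE 0.19). Itga2b, the integrin chain CD41, read 7.25 ± 0.10 against 7.59 ± 0.23, and the chemokine gene Pf4 6.71 ± 0.34 against 7.19 ± 0.29. Gp9 and Ppbp, 2 further platelet genes, differed by -0.02 and 0.02. Only 4 members had an unadjusted p under 0.05, all lower, and 0 were called when adjusted over the list alone or over all probe sets. The mean deviation of the list was -0.12, -0.14 and 0.03 in knockout replicates 1 to 3 and 0.03, -0.02 and 0.22 in wild-type replicates 1 to 3 (exact permutation p = 0.3). The median was -0.08 without wild-type replicate 3 and -0.20 without knockout replicate 3.

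Erythroid genes had mostly small positive differences. Of 30 measured members 23 were above 0, with a median of 0.06 (camera adjusted p = 0.0438, p = 0.391 with an estimated correlation), and 0 had an unadjusted p under 0.05. The membrane skeleton genes Epb42 and Sptb differed by 0.25 (SE 0.14) and 0.16 (SE 0.11). Klf1, an erythroid transcription factor gene, differed by 0.12 and the erythropoietin receptor gene Epor by 0.11, while Gata1 differed by 0.01. Without knockout replicate 2, knockout replicate 3 or wild-type replicate 1 the list was no longer called (adjusted p = 0.258, 0.551 and 0.327), nor with each array centred on its median (0.103). The median was 0.02 without knockout replicate 3 or wild-type replicate 1 and 0.10 without knockout replicate 1. It was 0.05 without knockout replicate 2 and 0.06 with centred arrays.

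B cell genes were higher as a group in camera's test. The median of 23 measured members was 0.13, with 16 above 0 (adjusted p = 0.0310, p = 0.170 with an estimated correlation), and 0 had an unadjusted p under 0.05. Cd79a, a chain of the B cell receptor, read 7.35 ± 0.43 in knockout and 6.79 ± 0.37 in wild-type arrays, and Ighm, the IgM heavy chain, 8.83 ± 0.62 and 8.19 ± 0.69. Cr2 and Vpreb2 differed by 0.21 and -0.25. The mean deviation of the list was 0.12, -0.10 and 0.24 in knockout replicates 1 to 3 and -0.03, -0.26 and 0.03 in wild-type replicates 1 to 3. The call was lost without knockout replicate 1, knockout replicate 3 or wild-type replicate 2 (camera adjusted p = 0.248, 0.0842 and 0.217). It was also lost with array weights (0.298). The median was 0.10, 0.08 and 0.10 without these arrays in turn, and 0.12 with array weights.

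**Figure D2:**
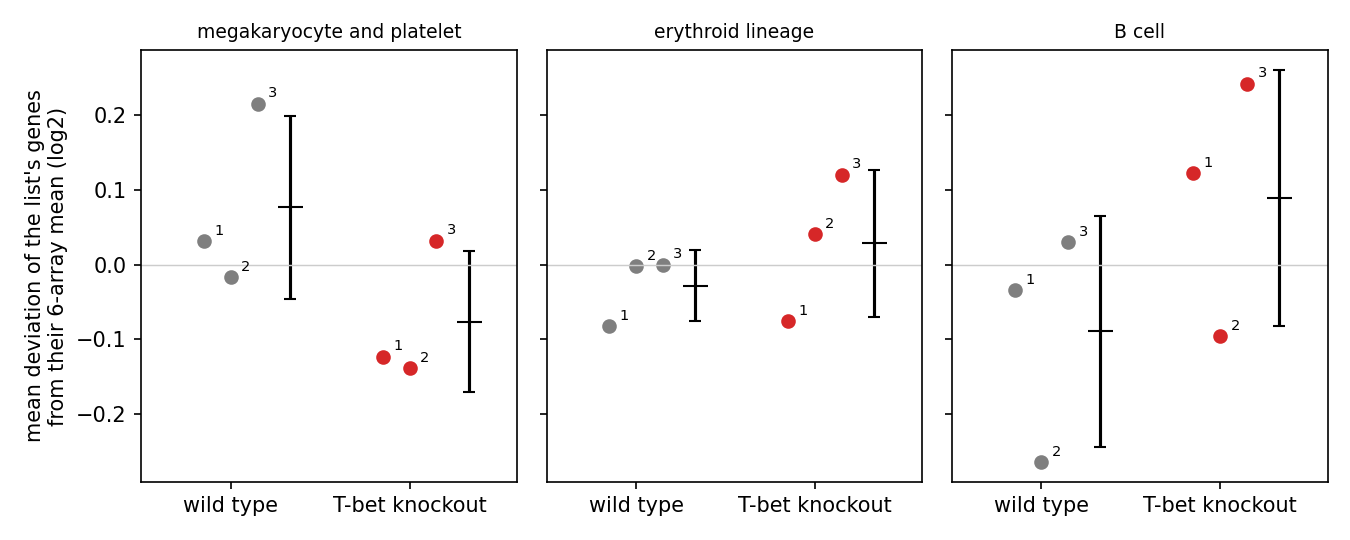
Mean deviation (vertical axis, log2) of the genes of the megakaryocyte and platelet, erythroid and B cell lists from their own 6-array mean, by genotype (horizontal axis), with 1 numbered point per array and the group mean ± SD in black. Groups overlap in all 3 panels, with the highest megakaryocyte value, 0.22, in wild-type replicate 3.

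The other 21 lists did not pass camera's test, and 0 of their genes were called over a list alone or over all probe sets. With an estimated correlation 0 of the 24 lists were called (smallest adjusted p = 0.964), and fry called 0. At the preset correlation 10 of the 21 were called in at least 1 alternative, as given with each. Globins, of which 6 embryonic or minor members were measured, had a median of 0.03 and a mean of -0.02 (camera adjusted p = 0.909), with Hbb-bh1 at -0.37, Hbb-y at 0.26 and Hbq1b at -0.23. Heme synthesis and iron uptake genes had a median of 0.01 (21 genes, adjusted p = 0.770), with Ppox, Urod and Fech at 0.15, 0.11 and 0.17, and were called higher without knockout replicate 1 (0.0118).

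Stem and multipotent progenitor genes had a median of -0.03 (31 genes, adjusted p = 0.497). Tek, the angiopoietin receptor gene, read 5.92 ± 0.08 in knockout and 6.39 ± 0.13 in wild-type arrays, Hoxa10 differed by 0.24 and Robo4 by -0.20. Progenitor growth factor receptors and kinases, a list that also holds Tek, had a median of -0.00 (25 genes, adjusted p = 0.909), with Acvr2a at 0.16 and Pdgfrb at -0.21.

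Among markers of other blood cells, granulocyte and monocyte genes had a median of -0.01 and a mean of 0.02 (42 genes, adjusted p = 0.619), with Csf3r, Lyz1 and S100a8 at -0.19, 0.20 and 0.39. Macrophage and dendritic genes had a median of -0.06 (27 genes, adjusted p = 0.497), with the complement genes C1qa and C1qc at -0.31 and -0.18 and Ciita at -0.21; they were called lower without knockout replicate 1 (0.0315). Mast cell, basophil and eosinophil genes had a median of -0.02 (27 genes, adjusted p = 0.909), with Ear6, Hdc and Mcpt8 at 0.43, 0.18 and -0.35. T and NK cell genes had a median of 0.04 (26 genes, adjusted p = 0.619), with Cd4, Lat and Nkg7 at 0.27, -0.27 and -0.28. Endothelial and stromal genes had a median of -0.02 (24 genes, adjusted p = 0.619), with Col1a2, Stab2 and Flt4 at -0.39, -0.27 and -0.25; they were called lower with the class of sex-linked signal as a block (0.0313).

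Genes that T-bet regulates in lymphocytes had a median of -0.03 (33 genes, adjusted p = 0.619) and were called lower with the class of sex-linked signal as a block (0.0313). S1pr5, a sphingosine phosphate receptor gene, read 6.63 ± 0.15 in knockout and 7.01 ± 0.05 in wild-type arrays, and Prf1 and Tnf differed by 0.29 and -0.17. Interferon response genes had a median of 0.06 (58 genes, adjusted p = 0.324). They were called higher in 5 alternatives: array weights (0.00559), without dim probe sets (0.0370), without knockout replicate 1 (0.0118), without wild-type replicate 2 (0.00601) and the sex-linked block (0.0134). The chemokine genes Cxcl9 and Cxcl10 differed by -0.29 and -0.26, and Stat2 by 0.27. Interferon-gamma and STAT signalling components had a median of 0.01 (27 genes, adjusted p = 0.816), with Pias3 at 0.17 and Il27ra at -0.12.

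Growth and stress lists had medians between -0.03 and 0.02. S phase genes had a median of 0.01 (42 genes, adjusted p = 0.619; Gins3 0.18, Pole -0.14, Cdc45 0.13) and mitosis genes 0.02 (46 genes, 0.497; Ccna2 0.23, Pttg1 0.21, Ttk 0.14). Without knockout replicate 1, without wild-type replicate 2 and with the sex-linked block both were called higher (S phase 0.00284, 0.0491 and 0.00911, mitosis 1.05e-05, 0.0221 and 0.00361). Mitosis was also called with array weights (0.0138). The fit with 1 knockout array, replicate 3, against wild-type replicates 2 and 3 called it too, but cannot tell genotype from that array. The p53 response and cell cycle inhibitor list had a median of -0.01 (27 genes, adjusted p = 0.909), with Fas, Rb1 and Pmaip1 at -0.26, 0.11 and -0.19. Apoptosis regulators had a median of -0.03 (30 genes, 0.497), with Hrk at -0.24, and were called lower without knockout replicate 3 (0.0416). Immediate early and handling stress genes had a median of 0.01 (42 genes, adjusted p = 0.619), with the heat shock genes Hspa1a, Hspa1b and Hspb1 at 1.66, 1.32 and -0.25. The list was called higher without knockout replicate 2 (0.00294) and lower without knockout replicate 3 (0.0416). It was also called higher in the fit with 1 knockout array, replicate 3, which had the list's highest mean deviation, 0.44. Ribosomal protein genes had a median of 0.01 (56 genes, 0.619), with Rpl9, Rps23 and Rpl37a at -0.29, 0.24 and -0.18, and were called higher without wild-type replicate 2 (0.0107) and with the sex-linked block (0.0119). Respiratory chain genes had a median of -0.02 (61 genes, 0.619; Cox8a -0.17, Cox5b -0.18, Cycs -0.12) and unfolded protein response genes -0.01 (27 genes, 0.909; Ddit3 0.32, Sec61b -0.27, Syvn1 0.11).

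**Figure D3:**
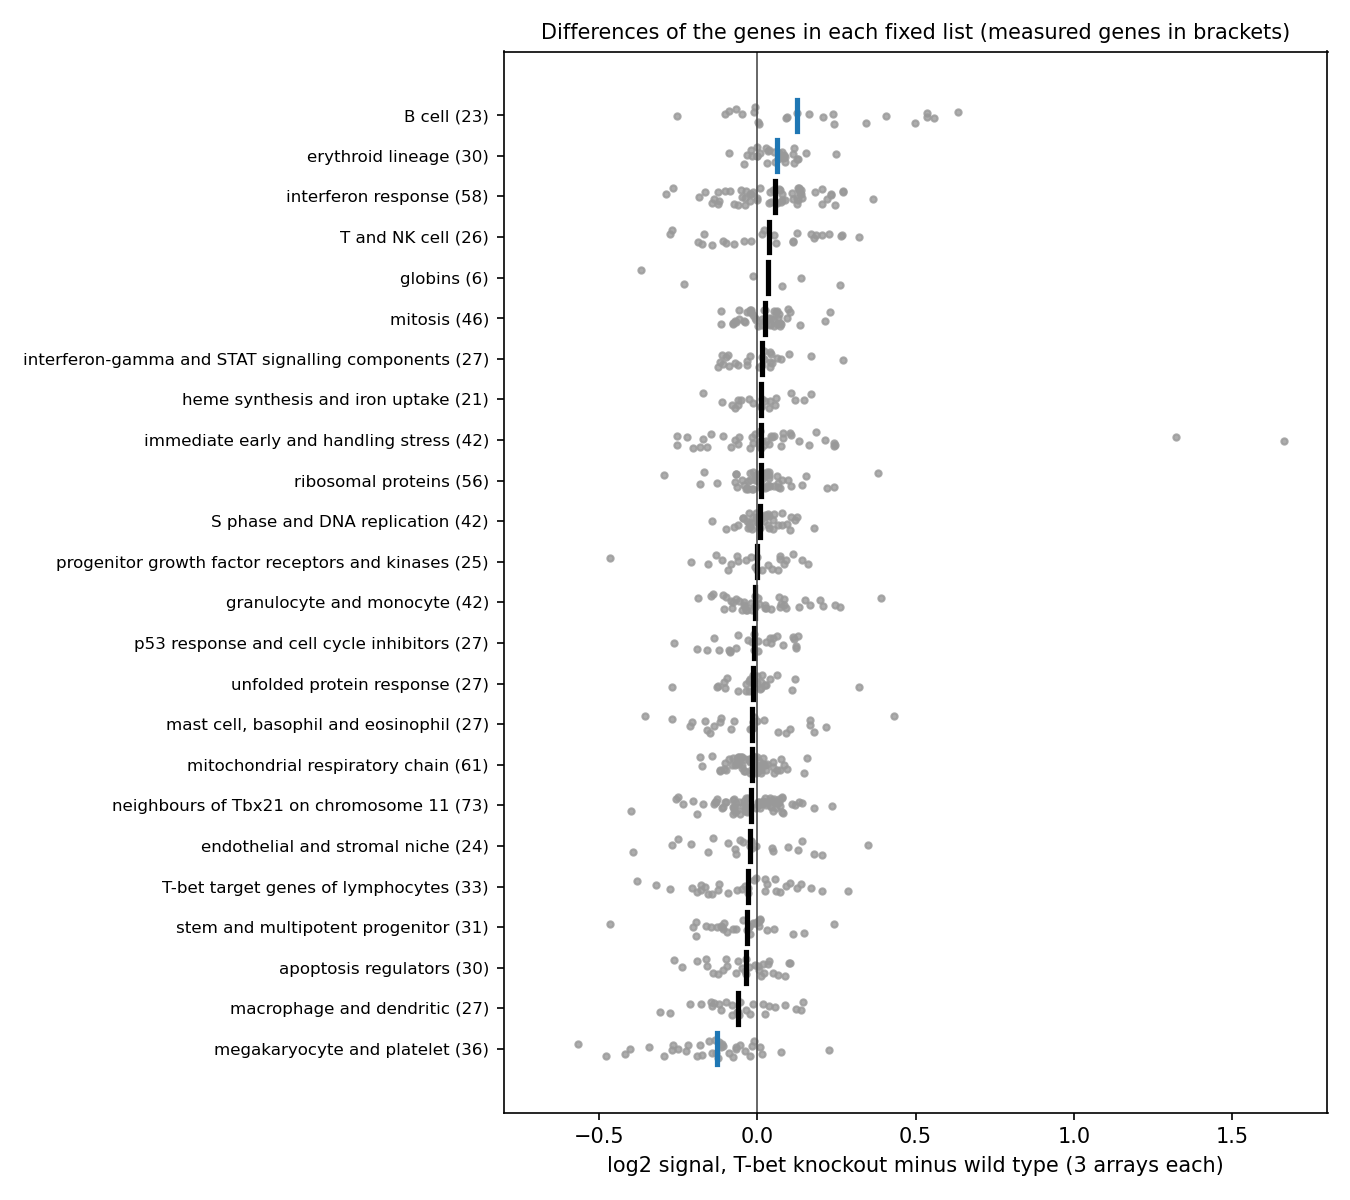
Difference in log2 signal between knockout and wild-type arrays (horizontal axis) of every measured gene of the 24 fixed lists (rows, grey points), with the list's median as a bar, blue where camera's adjusted p was under 0.05 at the preset correlation. Medians run from -0.13 for megakaryocyte and platelet genes to 0.13 for B cell genes.

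A knockout made in stem cells of another strain can carry that strain's DNA around the targeted gene, so genes near Tbx21 on chromosome 11 were examined. The fixed list of 73 measured neighbours had a median of -0.02 (camera adjusted p = 0.619), with Igfbp4, B4galnt2 and Hoxb5 at -0.40, 0.24 and -0.25. Within 10 Mb, 4 of 416 genes had an unadjusted p under 0.01 (0.962%), against 84 of 21577 elsewhere (0.389%), an odds ratio of 2.48 (95% interval 0.658 to 6.65, Fisher's exact p = 0.0857). They were Rsad1, Nags, a urea cycle gene at -0.47 (SE 0.09), the clone C130046K22Rik at -0.60 and Rapgefl1 at 0.51. Windows of 5 and 20 Mb gave odds ratios of 1.88 (Fisher's exact p = 0.294) and 1.81 (p = 0.212). In 6 of the 15 alternatives of the 10 Mb window Fisher's exact test passed 0.05, among them after a further quantile normalization (odds ratio 3.34, p = 0.0119), without dim probe sets (4.85, p = 0.0123), without wild-type replicate 2 (4.94, p = 0.00476) and with limma-trend (5.95, p = 0.00227). Without knockout replicate 1 the odds ratio was 1.44.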

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

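No scaling moved the median difference of all probe sets by 0.1, which says little because these scalings bring the array medians together. A further quantile normalization did change the balance of the unadjusted list, from 126 higher and 54 lower to 79 and 70. Tbx21 kept its direction and stayed short of the threshold in all 15 alternatives, as did the 20 named genes wherever they were measured. The direction of those 20 was all but fixed by the rule that their groups not overlap. Probe sets past adjusted p 0.05 numbered 1 with each array centred on its median, 1 with array weights, and 0 to 2 when 1 array was left out (2 without knockout replicate 3). With the threshold loosened to 0.1 there was 1 probe set. The unadjusted count of 180 was 60 without dim probe sets and 35 for named probe sets alone. Those fits held 28940 and 25335 of the 41345 probe sets, so the counts fell by more than the number tested. The count was 79 at an unadjusted p under 0.05 and 2-fold, which loosened the p and raised the fold. It was 326 with the sex-linked block and 194 to 307 when 1 array was left out (307, 296 and 287 without knockout replicates 1 and 2 and wild-type replicate 1). The replicate block gave 229 and changed no call, with adjusted p of 3.08e-07, 8.59e-05 and 0.0277 for the megakaryocyte, B cell and erythroid lists.

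The 3 called lists became 9 with the sex-linked block, 2 to 7 when 1 array was left out (7 without knockout replicate 1, 6 without wild-type replicate 2), and 0 with an estimated correlation, with fry, and with the replicate block and an estimated correlation. The adjusted p of the megakaryocyte list was 0.964, 0.948 and 0.460 in these last 3, with 1.88e-09 to 0.00659 when 1 array was left out. For the B cell list it was 0.964, 0.948 and 0.460, 0.298 with array weights, and 0.000555 to 0.248. For the erythroid list it was 0.964, 0.948 and 0.90, 0.103 with centred arrays, and 0.000261 to 0.551. The odds ratio near Tbx21 was 3.34 after quantile normalization, 5.95 with limma-trend, 4.85 without dim probe sets, 3.21 with the sex-linked block, 2.72 for named probe sets alone, and 1.44 to 4.94 when 1 array was left out. The 3 arrays with 1 sex's signal hold a single knockout array, replicate 3, against wild-type replicates 2 and 3, and the lone array is assumed to vary like the others. That fit gave 721 probe sets past the unadjusted threshold, an adjusted p of 0.504 for the megakaryocyte list and an odds ratio of 0.791, and bears on neither sex nor the flank. The sex-linked block, the 3 arrays, the named probe sets and the blocked estimated correlation were chosen after seeing the data, and the cause of each shift was not tested unless named. Signal over background is unknown here and limits what the dim probe sets show.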

Other observations

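Of the tests below, those of the sex-linked signal and of other lineages, and the sex-linked block, were chosen only after the result was seen. Leaving out wild-type replicate 3 and the test of genes near Tbx21 were planned, and how to read them was set afterwards.

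Several list means were lowest in the same replicate number of both genotypes. Of the 42 measured immediate early and handling stress genes, 24 were lowest in replicate 2 of each genotype and 18 were not, Egr2 among the latter. As examples of the 24, picked after their values were seen, Egr1 read 8.12, 7.39 and 8.86 in knockout replicates 1 to 3 and 8.59, 7.24 and 8.57 in wild-type replicates 1 to 3. Zfp36, whose protein degrades cytokine mRNA, read 7.90, 7.10 and 8.90 in knockout and 8.67, 7.19 and 8.59 in wild-type arrays, and Cd69 6.42, 6.18 and 7.65 against 7.34, 6.19 and 7.47. The mitosis list deviated by -0.17 in knockout replicate 1 and -0.11 in wild-type replicate 1, and the heme list by -0.15 and -0.11. In 18 of the 24 lists the lowest knockout and the lowest wild-type array bore the same number, where unrelated numbers and independent lists would give 8; the lists are not independent. In contrast, 5 of the 24 lists differed between genotypes in the same direction in all 3 numbers, where chance gives 6. The megakaryocyte list was among them, at -0.15, -0.12 and -0.18 for numbers 1 to 3, and the B cell list, at 0.16, 0.17 and 0.21.

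The heat shock gene Hspa1a had the largest difference of any gene in the lists, 1.66 (SE 0.66), with 9.15, 10.27 and 11.59 in knockout and 9.60, 8.13 and 8.28 in wild-type arrays. The groups overlapped, limma's adjusted p was 1, and Hspa1b, at 1.32, is a near-identical paralog, so the pair counts as 1 uncertain observation. The B cell genes Ebf1, Il7r and Dntt, picked after their values were seen, differed by 0.54, 0.50 and 0.54, and each read highest in knockout replicate 3 and lowest in wild-type replicate 2. In all, 8 of the 23 members had these extremes, Cd79a, Ighm, Blnk, Igll1 and Vpreb3 among them, and 15 did not; the list's estimated inter-gene correlation was 0.135. The median difference over all odorant and vomeronasal receptors was 0.08.

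Xist and Y-linked genes were both high in 3 of the 6 arrays. Probe sets blind to sex are argued against: each Y-linked gene lay at least 2.65 log2 above its level in wild-type replicate 2 on these arrays. RNA of both sexes on 1 array is consistent with the intermediate Y-linked signal, which was 0.386, 0.456 and at most 0.498 of that in the 2 arrays without Xist. The Xist shares were 0.766, 0.743 and 0.753 of that in wild-type replicate 2, so both shares summed to 1.15, 1.20 and 1.25, above the 1 of a linear mixture, and the proportions stay unknown. Pooled mice, mixed bone marrow or mixed RNA would each give this, and none was told from the others. No biological explanation was tested.

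Megakaryocyte genes lower in the knockout could reflect wild-type replicate 3, whose list mean was the highest. Without that array camera's adjusted p was 0.00659 (range over all alternatives 1.88e-09 to 0.964) and the median -0.08, so that array carried part of the shift. Camera's p counts genes as nearly independent and cannot exclude that the rest is spread between arrays. The remaining list means overlapped, at 0.03 and -0.02 in wild-type replicates 1 and 2 and -0.12, -0.14 and 0.03 in knockout replicates 1 to 3. With the class of sex-linked signal as a block the median was -0.13, so the shift remained within classes. That fit takes no information from wild-type replicate 2, which is alone in its class, and rests on wild-type replicates 1 and 3. Setting the arrays with both sexes' signal, knockout replicates 1 and 2 and wild-type replicate 1, against the others gave a median of -0.130. The real split gave -0.126, so a part of sex in the shift stays open. Knockout replicate 3 alone against wild-type replicates 2 and 3, which differ in that class, gave a median of -0.03 and cannot weigh sex. The list mean of knockout replicate 3 differed by -0.18 from that of wild-type replicate 3, of its own class. More cells of other lineages in the knockout sort stay open: 2 of the 5 lists of such markers had a median above 0. Of the 10 splits of the 6 arrays, 2, the real one included, gave a megakaryocyte p as small (real 5.09e-07, lowest other 1.77e-11), and 10 splits cannot give a share under 0.05. The split with that lowest p, knockout replicates 1 and 2 with wild-type replicate 2, also had a larger median, -0.177. An effect of T-bet loss on megakaryocyte transcripts remains a hypothesis, untested beyond these arrays.

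The same splits bear on the counts, and for none of them can 10 splits give a share under 0.05. All 10 splits gave 0 probe sets past limma's adjusted p of 0.05. Since the real count was 0, every split was bound to be as large, so that tally decides nothing. A total of 3, the real one included, gave at least the real 180 probe sets past the unadjusted threshold. The highest other, 522, set knockout replicates 1 and 2 and wild-type replicate 1 apart, the arrays with both sexes' signal. With that class as a block the real count was 326, but wild-type replicate 2, alone in its class, then adds nothing to the contrast. The count also rose, to between 194 and 307, when 1 array was left out. The 326 is therefore no evidence on sex. As many lists as the real 3 were called in 9 of the 10 splits, up to 15. That highest split joined knockout replicate 1 with wild-type replicates 1 and 3, and also had the most probe sets at an unadjusted p under 0.05, 3672 against 3166 in the split by both sexes' signal and 2033 in the real one. Larger counts than the real ones can come from chance or from a structure of the samples, and 10 splits cannot tell these apart. Among the 4 splits that part all 3 same-numbered pairs, the others gave 97, 114 and 180 probe sets and 9, 1 and 4 lists. Their megakaryocyte p-values were 0.122, 0.0181 and 0.232, so among these 4 the real split had the smallest, and 4 splits cannot exclude chance.

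Rsad1, Nags and C130046K22Rik, all within 10 Mb of Tbx21, were lower in all 3 knockout arrays than in any wild-type array. Rapgefl1, also within 10 Mb, was higher in all 3. The groups did not overlap for 8.70% of all genes, and the naming rule required it of Rsad1, so non-overlap is no evidence here. DNA of another strain around the targeted gene may alter the binding of these genes' probes or their expression. The odds ratio of 2.48 within 10 Mb (Fisher's exact p = 0.0857) leaves this open, since few neighbours need differ. Sequencing of the flank would show whether such DNA is present, but not whether it causes these differences. Neither an effect of T-bet on these genes nor chance was told apart from an effect of that DNA.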
